A study of Spinacia oleracea with 6 samples.

How the data were processed

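Root tissue of spinach grown in nutrient solution was sampled. Per the labels' protocols, plants were raised for 3 weeks on sand, acclimated for 3 weeks in solution with 2 µM zinc sulphate, and then treated for 3 weeks. The study prepared 9 zinc treatments, of which the 500 µM nano and 500 µM bulk zinc oxide roots were sequenced. Roots were collected 1 day before harvest. RNA was extracted with Trizol and libraries were made with the TruSeq RNA kit. The 6 libraries fall into 2 groups of 3 by their titles. The labels call the samples biological replicates. They do not say whether each came from 1 plant or 1 pot, so p-values measure the spread between these samples.

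The authors deposited 1 table per library with an RPKM value (reads scaled to the length of the contig and to the mapped reads of the library) for each of 147733 contigs, the same contigs in each table. Per the file headers, 5 of the columns are RPKM. The column of nano replicate 2 has no unit in its heading, and its values follow the same read steps as the others. CASAVA 1.8.2, an Illumina base-calling and demultiplexing package, is named in the submitters' processing notes. The assembler, the mapper and their settings are not given in the sources used here. Per the contig names in the files, the contigs carry the name of the library of nano replicate 2, of which the text keeps the last part. That library has 41522 contigs at 0, so its reads alone do not account for the contig set. In all, 2 of the tables end in a blank row, which was left out. A contig assembled without a genome can be a part of a transcript, and similar transcripts can share reads, so a contig is not the same as a gene. None of the contig names matched the gene table of the spinach genome (39719 genes). The 20 gene lists prepared before the data were examined (metal transport, antioxidant enzymes, defence, cell wall and others, with cell type and contamination markers) were therefore not tested.

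RPKM hides the depth, so the reads behind the values were recovered. Low values in different libraries stood in ratios of whole numbers, which gave the relative depth. The read steps of different contigs were multiples of a common step, which gave the library totals and contig lengths, assuming whole lengths of at least 200 bases. The recovered totals were 38.6, 32.3 and 33.7 M reads for nano replicates 1 to 3 and 29.2, 29.8 and 31.0 M reads for bulk replicates 1 to 3. The recovered reads on contigs summed to 99.5 to 99.6% of these totals. Each contig took the shortest length that gave whole reads in all libraries, so the 99.1% of values above 0 within 0.001 of a whole read are partly a product of that search. A first solution had totals smaller by a factor of 2. It also gave a length for each contig with a read, but its reads summed to 1.98 times the totals, and it was replaced. Absolute reads, depths and lengths rest on that choice and on the minimum of 200 bases, and the relative depths of the libraries do not. A contig whose reads share a common factor can be understated by that factor. Tested on simulated data with known reads over 147733 contigs, the procedure returned all 6 library totals and, for contigs at 1 RPKM or more in 3 libraries, the exact reads of 99.3%. The recovered reads give the depth, the thinned values and an added alternative. Intervals from reads cover counting error only.

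The comparison of nano with bulk was run on log2(RPKM + 1), on contigs with at least 1 RPKM in at least 3 of the 6 libraries, with limma 3.58.1 in R 4.3.3 (empirical Bayes with a trend on abundance, two-sided, Benjamini-Hochberg adjustment over the tested contigs, threshold 0.05). The design listed a count test for the case of deposited counts. As the authors deposited RPKM, the limma test listed for normalised values was used. A fold change on this scale understates the change of scarce contigs. The rule for named contigs, where contigs carry no gene names, was the 2 with the smallest p in each direction. This test was tried on simulated reads for the real contigs with 200 changed contigs. It called 94 of 100 contigs changed 4-fold and 31 of 100 changed 2-fold, along with 7 unchanged contigs among 29597 tested. The variances were drawn from the fitted prior. This model of the spread replaced an earlier one with the moderated variance of each contig, after the result of that model had been seen; with the earlier model 56% of the 2-fold and 99% of the 4-fold contigs were called. The simulated replicates vary independently between contigs, which real libraries need not do. Single values per library were compared with exact permutation tests over all divisions of the libraries. Analyses outside limma used Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3.

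The reads of all 15 pairs of libraries were compared to look for duplicated libraries. The chi-square per degree of freedom lay between 32.7 and 105, so no pair agreed within sampling noise. That does not bear on whether the samples are biologically independent. Replicate numbers are shared by both groups, and nothing in the labels says that a number marks a shared pot or day. The alternatives fixed before the data were examined were limma without the trend, quantile normalisation, no filter, a filter at 5 RPKM, a pseudocount of 0.1, an adjusted p of 0.01, the replicate number as a block, and each library left out in turn. Alternatives added after seeing the data were voom on the recovered reads, reads thinned to 1 depth, the number of contigs detected as a covariate, all those for the contigs detected, and most of those for the similarity of libraries. The results of voom, of the planned fits and of the splits of the libraries were known when these were listed, and those of the thinned reads and the covariate were not. The planned result is the number of contigs at an adjusted p under 0.05. The number at an unadjusted p under 0.05, the abundance classes, the contigs without overlap, those present in 1 group alone, the contigs detected per library and their relation to the principal components were taken up afterwards.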

Results

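Roots of hydroponically grown spinach (Spinacia oleracea, line N1L1) were compared after exposure to zinc oxide as nanoparticles (nano) or in its ordinary bulk form (bulk). Both forms were given at the same nominal dose of 500 µM. Each group had 3 root samples, described in the labels as biological replicates. RNA libraries of the TruSeq type were sequenced in 1 lane of an Illumina HiSeq2000. Transcript abundance was given as RPKM for 147733 assembled contigs per library. A contig is a sequence assembled from overlapping reads. The contigs carried only a number, so their genes, genomic positions and functions are not reported, and the comparisons below concern numbered contigs and groups of contigs. No library from plants without added zinc oxide was analysed here, so the values compare the 2 forms with each other and not with untreated roots.

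The libraries held between 29.1 and 38.4 M reads on contigs, as recovered from the steps between the RPKM values. Nano replicates 1, 2 and 3 had 38.4, 32.2 and 33.6 M reads. Bulk replicates 1, 2 and 3 had 29.1, 29.6 and 30.9 M reads. Each nano library was therefore deeper than each bulk library (34.7 ± 3.27 against 29.9 ± 0.942 M reads, SD, n = 3 each), with an exact two-sided permutation p of 0.1, the smallest that 3 against 3 samples can give. Of all contigs, 30450 (20.6%) reached 1 RPKM in 3 or more libraries and were tested. These tested contigs took up 98.6% of the assigned reads, with a median of 999 reads per contig over the 6 libraries. Their recovered median length was 999 bases, against 376 bases for all contigs with a read.

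The first question was which root transcripts differ between nano and bulk zinc oxide at the same dose. No tested contig passed the threshold. The contig with the smallest p, contig_3871, had about 3 times the abundance in nano roots (81.5 ± 19.8 RPKM, SD, n = 3) that it had in bulk roots (26.9 ± 2.47 RPKM, SD, n = 3). With limma and Benjamini-Hochberg adjustment, 0 of 30450 contigs had an adjusted p under 0.05, and the smallest adjusted p was 0.40. At an unadjusted p under 0.05 there were 3529 contigs, where 1522.5 would be expected with no difference. Of these, 2155 had higher and 1374 had lower values in nano roots. Leaving out a library gave between 1701 (5.74% of those tested, without nano replicate 3) and 4761 (16.2%, without nano replicate 1), with 2287 without nano replicate 2. With no filter it was 6675, which is 4.52% of 147641 contigs and under the 5% of uniform p-values, and 3099 of the 3529 were among them. Without bulk replicate 2 there were 3741, split into 1827 higher and 1914 lower, and with no filter 3220 were higher and 3455 lower. The RPKM values summed to more in each nano library (662828 to 682140) than in each bulk library (649235 to 659420). With quantile normalisation 1906 were higher and 1663 lower. The count at an unadjusted p was taken up after no contig had passed the threshold. The voom method of limma, run on the recovered reads, also gave 0 contigs at an adjusted p under 0.05 and 3420 at an unadjusted p under 0.05. In data simulated at these depths, 100 contigs were changed 4-fold and 100 changed 2-fold at once. All were among contigs with a mean of at least 5 RPKM. The replicate variances were drawn from the fitted prior, not taken from each contig. The same test called 94% of the 4-fold and 31% of the 2-fold contigs. With another model of the replicate spread it called 99% and 56%. Many changed contigs at once ease the Benjamini-Hochberg cut-off, so these shares do not give the power for a lone changed contig.

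The 4 contigs named by the rule fixed beforehand had separate values in the 2 groups, but their differences did not survive adjustment for the number of contigs tested. These contigs were picked for the smallest p in the same data, so their fold changes and intervals carry that selection. contig_3871 (recovered length 1345 bases) lay between 65.9 and 103.9 RPKM in the nano libraries and between 24.9 and 29.6 RPKM in the bulk libraries. Its log2 fold change was 1.54 ± 0.18 (SE; 95% interval 1.13 to 1.96; limma adjusted p = 0.40). contig_19889 (584 bases) was a scarce transcript with 2.23 ± 0.181 RPKM in nano and 0.230 ± 0.158 RPKM in bulk roots (SD, n = 3 each). It rested on 136 reads in the nano and 12 reads in the bulk libraries, a ratio of 9.75 after scaling to the library totals, with an exact 95% interval of 5.40 to 19.3 that covers counting error only. Its log2 fold change on the log2(RPKM + 1) scale was 1.40 ± 0.17 (SE; limma adjusted p = 0.40), against 2.92 with a pseudocount of 0.1 and 3.29 with voom.

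On the other side, contig_1686 (1286 bases) had 26.9 ± 1.24 RPKM in nano and 46.4 ± 4.18 RPKM in bulk roots (SD, n = 3 each), a log2 fold change of -0.76 ± 0.11 (SE; 95% interval -1.02 to -0.50; limma adjusted p = 0.40). contig_24300 (779 bases) had 12.4 ± 2.56 RPKM in nano and 26.8 ± 1.87 RPKM in bulk roots (SD, n = 3 each), a log2 fold change of -1.07 ± 0.16 (SE; 95% interval -1.45 to -0.69; limma adjusted p = 0.40).

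**Figure D1:**
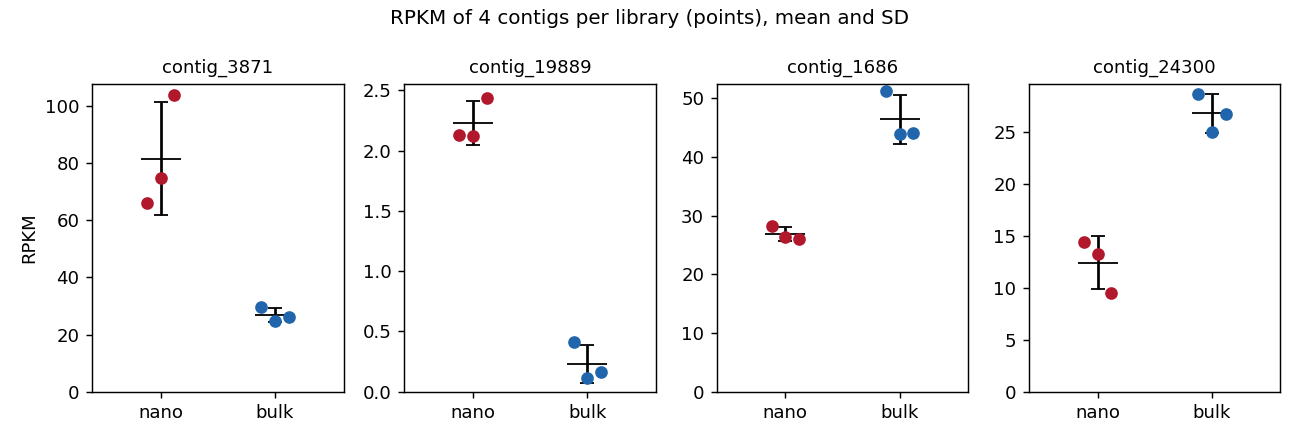
RPKM of the 4 named contigs in the 3 nano (red) and 3 bulk (blue) libraries; points are libraries, the horizontal line is the group mean and the bars are the SD, and each panel has its own axis from 0. The nano points of contig_3871 and contig_19889 lie above all bulk points, and those of contig_1686 and contig_24300 lie below them.

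Differences were small for most transcripts. The median size of the log2 difference over the 30450 tested contigs was 0.19, and the median standard error was 0.19. Setting these medians side by side does not test whether the differences exceed noise. The log2(RPKM + 1) scale also understates the change of scarce contigs. Higher-abundance contigs had smaller replicate spread and more often a small p. Of the 5871 contigs with a mean of 20 RPKM or more, 1287 (21.9%) had an unadjusted p under 0.05, 768 of them higher and 519 lower in nano roots. Of the 9889 contigs with a mean of 5 to 20 RPKM, 1260 (12.7%) did so, 797 higher and 463 lower. Of the 14690 contigs with a mean under 5 RPKM, 982 (6.68%) did so, 590 higher and 392 lower. None of the contigs in any of the 3 classes had a limma adjusted p under 0.05. These classes, and the counts of contigs without overlap or present in 1 group alone, were chosen after the data had been seen.

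The values of nano and bulk libraries did not overlap for 17.8% of the tested contigs, where chance gives 10% for 3 against 3 and the other 9 splits of the 6 libraries into 3 and 3 gave between 4.34% and 20.3%. A contig with distinct values lacks overlap in exactly 1 split. A higher share in the real split therefore lowers the others, which are not an independent reference. A log2 difference of at least 1 without overlap was present in 163 contigs, 95 higher and 68 lower in nano roots, and in 14 to 352 contigs in the other splits. Contigs present in 1 group alone were few. Of all 147733 contigs, 3 had at least 3 reads in each nano library and none in any bulk library, and 11 had the reverse, 14 in all against 11 to 78 in the other splits. The upper ends of these ranges (20.3%, 352 and 78) came from 1 split, nano replicate 1 and bulk replicates 1 and 3 against the rest. It parts the 3 libraries with the most contigs detected at 1 depth from the 3 with the fewest, so these upper ends do not measure chance alone. For a contig with 0 reads in a library, counting error alone allows up to 3 reads.

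**Figure D2:**
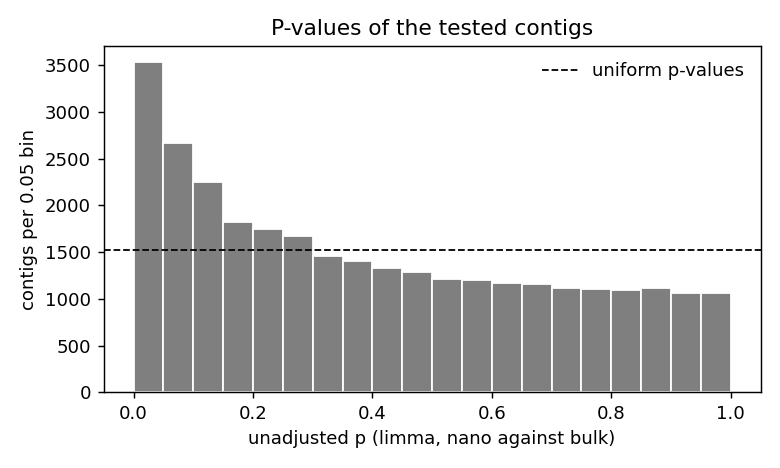
Number of tested contigs (vertical axis) per 0.05 interval of the unadjusted limma p for nano against bulk (horizontal axis); the dashed line is the number per interval if p-values were uniform, 1522.5. The first interval holds 3529 contigs, and the intervals from 0.3 upwards lie below the line.

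The second question was whether libraries of a group resemble one another more than they resemble the other group. The mean Pearson correlation of log2(RPKM + 1) across the tested contigs was 0.963 within groups (6 pairs) and 0.955 between groups (9 pairs). These correlations are across contigs, which are not independent replicates. The difference of 0.0074 was within what divisions of the libraries gave by chance (exact one-sided permutation p = 0.2; the smallest possible is 0.1). It was 0.013 over contigs with a mean of at least 5 RPKM (exact one-sided permutation p = 0.1, the smallest possible), and 0.0018 over 147641 contigs with no filter (exact one-sided permutation p = 0.4). Leaving out a library gave between 0.00055 (without nano replicate 3) and 0.013 (without nano replicate 1), with 0.0027 without bulk replicate 1 and 0.012 without bulk replicate 2. The highest correlation, 0.973, was between nano replicate 2 and bulk replicate 2. The lowest, 0.921, was between nano replicate 3 and bulk replicate 1. These libraries also stood at the ends of the first principal component, which held 40.4% of the variance.

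The number of contigs with a read in a library, looked at after the data had been seen, varied within both groups by more than the difference between the group means. With reads thinned to 29.1 M per library, nano replicates 1, 2 and 3 had reads on 109866, 103708 and 97438 contigs. Bulk replicates 1, 2 and 3 had reads on 114311, 99271 and 112521 contigs. The means were 103671 ± 6214 in nano and 108701 ± 8216 in bulk roots (SD, n = 3 each; exact two-sided permutation p = 0.4). Without thinning they were 107890 ± 8087 and 109401 ± 8354 (SD, n = 3 each; exact two-sided permutation p = 1), and nano replicate 1 then had the most, 116685. Contigs with a mean under 1 RPKM took 1.26 ± 0.154% of the reads in nano and 1.42 ± 0.410% in bulk roots (SD, n = 3 each; exact two-sided permutation p = 0.7). Among the 6 libraries, that share was highest in bulk replicate 1, at 1.85%. The 10 most abundant contigs of a library took 5.07 ± 0.809% of the reads in nano and 4.81 ± 1.17% in bulk roots (SD, n = 3 each; exact two-sided permutation p = 0.9). Over the 7 library measures compared in this way, depth included, the smallest Benjamini-Hochberg adjusted p was 0.70, that of depth, and the others were 1.

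**Figure D3:**
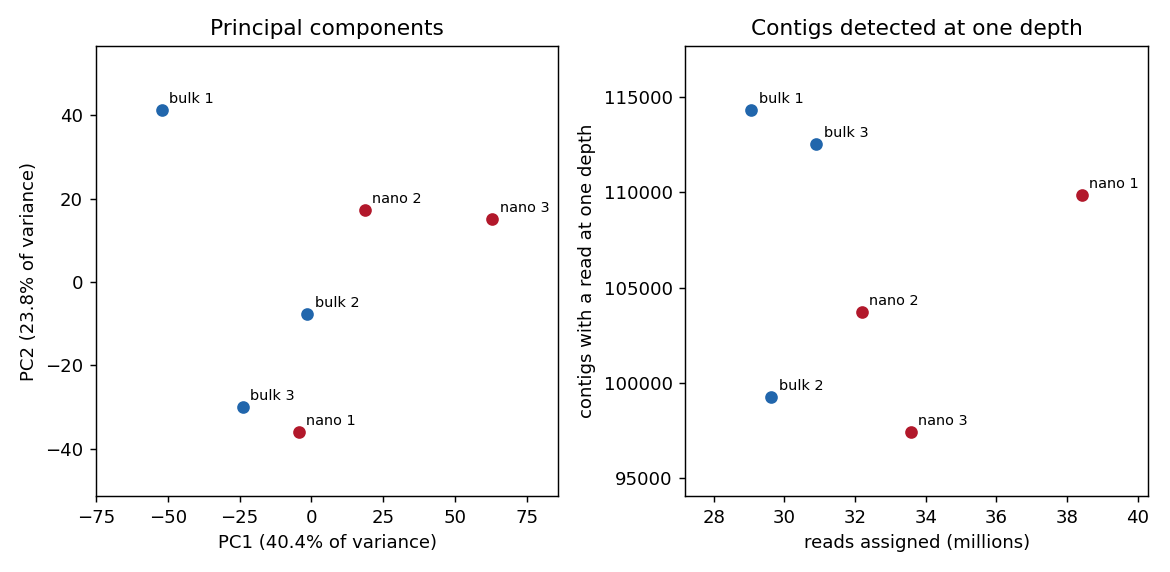
Left, the 6 libraries (nano red, bulk blue) on the first 2 principal components of log2(RPKM + 1) over the tested contigs, which hold 40.4% and 23.8% of the variance; right, the number of contigs with a read after thinning to 29.1 M reads (axis not from 0) against the reads assigned (M reads). Nano replicate 3 and bulk replicate 1 lie at opposite ends of the first component, and nano and bulk libraries are intermixed in the number of contigs detected.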

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

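The alternatives voom, thinned reads and detection covariate, the number of contigs detected with its alternatives, and those for similarity other than the 5 RPKM minimum were chosen after seeing the data. No contig passed an adjusted p of 0.05 under any of the 16 alternatives to the main test. The adjusted p of 0.01 among them reuses the main fit, which fixed its result. The smallest adjusted p lay between 0.19 (without nano replicate 1) and 0.77 (no filter). The 3529 contigs at an unadjusted p under 0.05 (11.6%) became 6675 with no filter. That was 4.52% of 147641 contigs, so over all of them the excess over the 5% of uniform p-values was absent. Of the 6675, 3099 were shared with the main test, above its 1522.5 expected by chance, so among its contigs the excess remained. Leaving out a library gave between 1701 (5.74%, without nano replicate 3) and 4761 (without nano replicate 1), and 2287 without nano replicate 2. Fewer libraries also lower the power. Under the other alternatives this number stayed within 1.5 times. Contigs higher in nano made up 61.1% of them, 53.4% with quantile normalisation, 48.2% with no filter and 48.8% without bulk replicate 2. With the replicate number as a block there were 3645 contigs, 2885 of them shared with the main test, and 0 at an adjusted p of 0.05. Deviations from group means correlated at -0.06, -0.08 and -0.05 for same-numbered libraries. Subtracting the group mean forces each library to have positive and negative partners, so a best match with another number followed from these negative values. The 4 named contigs kept their direction where tested (15 settings, 11 for contig_19889). Without overlap between groups, leaving out a library could not reverse it. Changing only trend, filter or block kept the estimate. The log2 fold change of contig_19889 lay between 1.33 and 3.29 (2.92 with a pseudocount of 0.1, 3.29 with voom). With a nano library left out, or at 5 RPKM, it did not pass the filter. The lead of within-group over between-group correlation stayed above 0 in 10 settings, between 0.00055 (without nano replicate 3) and 0.013 (a mean of at least 5 RPKM, exact one-sided permutation p = 0.1, the smallest possible), with 0.0018 with no filter (exact one-sided permutation p = 0.4). The mean number of contigs detected was lower in nano than in bulk in the main setting and in each of 8 alternatives. Nano minus bulk was -5030 in the main setting, -1511 at full depth and -3524 at 3 reads. Leaving out a library gave between -9745 (without bulk replicate 2) and -1914 (without nano replicate 3), with -8128 without nano replicate 1, -2225 without bulk replicate 1 and -3120 without bulk replicate 3. Not run were the count test and uniquely mapped reads (the values are RPKM), sums per annotation name, and all tests of the fixed gene lists and their members (contigs without names). Counting error alone leaves the ratio of contig_19889 between 5.40 and 19.3. The median standard error was 0.22 (log2) under 5 RPKM and 0.15 above 20 RPKM, and the part of depth in it was not separated.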

Other observations

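The tests of thinned reads and of the detection covariate were set down after the excess of small p-values had been seen but before their own results were. The settings that leave out a library or change the filter were fixed beforehand, but the count at an unadjusted p was not. All other tests in this part were chosen after the result was seen.

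The contigs with a small unadjusted p had different median lengths by direction, a difference that was not tested. The 2155 with higher values in nano roots had a median length of 1036 bases and a median log2 difference of 0.51. The 1374 with lower values had a median length of 1503 bases and a median log2 difference of -0.57. The median abundance was 12.3 and 13.2 RPKM, against 4.82 RPKM for the other tested contigs. An estimate from the p-values (limma, local false discovery rate method) put the share of contigs without a difference at 80.8%, treating contigs as independent. It rests on the excess of small p-values. A split that mixed the groups exceeded that excess (4076 contigs at an unadjusted p under 0.05 against 3529). That split set the 3 libraries with the most contigs detected at 1 depth against the 3 with the fewest, so it does not measure chance alone. Over all contigs with no filter the excess was absent, although 3099 of the 3529 kept an unadjusted p under 0.05. The estimate therefore does not give a share of contigs changed by the form of zinc oxide.

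More contigs had an unadjusted p under 0.05 than uniform p-values give (3529 against 1522.5, or 11.6% of those tested), and the share lay between 5.74% (without nano replicate 3) and 16.2% (without nano replicate 1) leaving out a library, at 15.8% with the filter at 5 RPKM and at 4.52% with no filter, where 3099 of the 3529 were included. Of the 10 splits of the 6 libraries into 3 and 3, 2 gave as many, the real one included, with 4076 the highest of the others, and 10 splits are too few for a share under 0.05. The split with 4076 set nano replicate 1 and bulk replicates 1 and 3 against the rest. These are the 3 libraries with the most contigs detected at 1 depth, so that split follows the number of contigs detected. At an adjusted p under 0.05 the real groups called 0 contigs and the highest other split 8. Counting noise from the deeper sequencing of the nano libraries is argued against as the whole cause. With reads thinned to 1 depth, 11.4% of the tested contigs still had an unadjusted p under 0.05, against 11.6% without. Thinning does not address other properties of a library that go with depth. Those cannot be told apart from the groups, as each nano library was deeper than each bulk library. With the number of contigs detected per library as a covariate the share was 8.58%, between the bounds set for and against that explanation, so it stays open, as does the form of the zinc oxide. The covariate also uses up a degree of freedom, which lowers the power, so the fall in the share does not by itself favour that explanation.

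The number of contigs detected followed the first principal component over the 6 libraries (Pearson r = -0.85, exact permutation p = 0.018; Spearman rho = -0.94, exact permutation p = 0.017), with an adjusted p of 0.054 for each over 6 relations. Without the 2 libraries farthest from the median number r was -0.65 and rho was -0.80. With only 4 libraries these were not tested.

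At 1 depth the libraries differ in how many contigs they detect, with the most in bulk replicate 1. Sequencing depth as the whole cause is argued against, since the range over libraries was 16873 contigs at 1 depth and 16930 at full depth, although thinning changed the library with most contigs (nano replicate 1 at full depth), the library with fewest (bulk replicate 2 at full depth, nano replicate 3 at 1 depth) and the group difference (-1511 to -5030). Reads on contigs private to any one library (over 90% of the scaled reads) are argued against as the whole cause, since the range at 1 depth was 16424 contigs without those contigs; of the reads on contigs with a mean under 1 RPKM, private ones made up 0.856% in bulk replicate 1 and between 0.206% and 5.14% over the 6 libraries. A uniform background over all contigs, as genomic DNA might give, stays open: the mean excess over the other 5 libraries at 0.5 to 1 RPKM was 2.92 times that at up to 0.1 RPKM in bulk replicate 1 (bootstrap 95% interval 2.75 to 3.09), but 0.701 times in nano replicate 1 (0.431 to 0.983) and of opposite sign in bulk replicate 3 (-0.0444 against 0.0450 RPKM). The rule written for this test covered only the library with most contigs, bulk replicate 1, whose whole interval lay on the side against a uniform background. The class between, 0.1 to 0.5 RPKM, was not part of the rule. There the excess of bulk replicate 1 was 0.0670 RPKM, below the 0.0868 RPKM at up to 0.1 RPKM, against 0.253 RPKM at 0.5 to 1 RPKM. The ratio of 2.92 thus does not describe a steady rise. The other libraries were weighed beside that rule, and they differ from bulk replicate 1. The form of zinc oxide stays open too (exact two-sided permutation p = 0.4 between groups). Other organisms, cell types and RNA handling were not tested.

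The most alike libraries belong to different groups, nano replicate 2 with bulk replicate 2 (r = 0.973), followed by nano replicate 1 with bulk replicate 3 and by nano replicates 2 and 3 (r = 0.972 for both). A candidate explanation is that the order of the sample numbers in the column headings tracks position or handling. Over the 15 pairs, similarity had a correlation of -0.30 with the distance between sample numbers. The exact one-sided p was 0.129 over the 720 orders of the numbers, so the question stays open. Deviations from group means correlated positively for nano replicate 1 with bulk replicate 3 (0.245), 2 with 1 (0.310) and 3 with 2 (0.233). All other nano and bulk pairs were negative. Subtracting the group mean forces each library to have positive and negative partners in the other group, so the presence of positive pairs is no evidence of shared handling. The sample numbers of the positive pairs lay 1, 2 and 16 apart, but nano replicate 3 was nearer to bulk replicate 1 (10). Whether the positive pairs mark shared handling was not tested, and no block by them was fitted.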
